A study of Rattus norvegicus with 15 samples.

How the data were processed

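RNA was sequenced from 15 libraries of GH3 cells, a rat pituitary tumour line, in 5 groups of 3: a control short hairpin RNA (shCtrl), the hairpins shFTO-2 and shFTO-3 directed against FTO, and the groups named OENC and FTOOE. Groups and replicate numbers were taken from the sample titles. OENC was taken as the control of the FTO overexpression group FTOOE because the names share the letters OE; the labels do not spell the abbreviation out. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

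Per the labels' protocols, total RNA was extracted with TRIzol, fragments were reverse-transcribed, and the complementary strand was made with dUTP before paired-end sequencing on an Illumina NovaSeq instrument. STAR and featureCounts are named, without versions, per the submitters' processing notes. The genome build, annotation, strand setting and handling of read mates are not given in the sources used here. The authors deposited whole-number counts per gene, not normalized, for 32623 Ensembl rat gene identifiers, of which 11575 had no count in any library. Total counts per library ranged from 22826691 to 29827305. Among identifiers at a count of 1 or 2, the share at 1 ranged from 25.7% (95% exact Clopper-Pearson interval 23.4 to 28.1) in shCtrl replicate 3 to 36.2% (33.6 to 38.9) in shFTO-2 replicate 3. These intervals cover counting error only. A count of 2 was therefore more frequent than a count of 1 in every library, as could arise if both mates of a fragment were counted. The totals given here may then be counts of mates, with fewer fragments behind each value than its count. An alternative with every count halved and rounded up was added for this reason. Without a stated strand setting, reads of overlapping or antisense genes and of near-identical copies cannot be separated here.

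The count table does not pair identifiers with gene names, and 0 of its identifiers matched the rat RefSeq gene table used (assembly GRCr8), in which 0 of 47357 genes carry an Ensembl identifier. The targeted gene Fto was therefore not analysed here, so knockdown and overexpression could not be checked from its counts. For the same reason the 28 gene lists fixed before the data were examined, and any check of gene length or GC content, were not used here. The planned rule for named genes ranked genes past the threshold, with a mean log2 CPM of at least 2 and with no overlap between the libraries compared, by their absolute log2 fold change (for the hairpins, the smaller of both). It also required a gene symbol; without symbols that condition was dropped, and only the first identifier in each direction is printed for knockdown and for overexpression.

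Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr (minimum count 10, minimum total count 15), robust dispersions and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 knockdown libraries, the 6 overexpression libraries, and all 15 libraries (for OENC against shCtrl and for the difference between overexpression and knockdown) were fitted separately, with group means only. Each fit assumed the same spread of a gene in all its groups. The shCtrl libraries lay further apart than those of the other groups, so this spread can be too small for tests against shCtrl. Standard errors were derived from the F statistic. CPM values of single identifiers are TMM-scaled. Correlations of fold changes are across genes, which are not independent replicates, and carry no p-value. The hairpin comparisons share the shCtrl libraries, as do OENC against shCtrl and the mean knockdown. For each pair, 20 data sets of unchanged groups were therefore simulated with the same sharing. Genes were drawn independently, with the spread of each gene pooled over the groups of the fit. A shift shared by many genes in the shCtrl libraries was not simulated, so these values can be too low for these controls. The test was also checked on simulated counts in which few genes were changed. For shFTO-2, shFTO-3 and FTOOE, 98, 99 and 99 genes were changed 2-fold and 97, 98 and 100 were changed 1.5-fold. Of genes changed 2-fold, 45.9% were recovered for shFTO-2 against shCtrl (13676 genes) and 66.7% for shFTO-3 against shCtrl (13687 genes). The share was 76.8% for FTOOE against OENC (13437 genes). Of genes changed 1.5-fold, 13.4%, 10.2% and 62.0% were recovered. Unchanged genes called numbered 7, 2 and 15. Beside the recovered genes (13 and 45, 10 and 66, 62 and 76), the first and last exceed a share of 0.05. With so few changed genes the adjustment is stricter than in the real data, so these recovery rates do not carry over. Principal components were computed on log2 CPM of the 14277 identifiers passing the filter over all 15 libraries. Chi-square values per degree of freedom between libraries of a group ranged from 4.43 to 156, so no library pair matched within sampling noise.

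Alternatives chosen before the data were examined were RLE size factors, library totals only, no filter or a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), a minimum absolute log2 fold change of 1, only genes of mean log2 CPM of at least 5 for the correlations, a replicate block, other sets of libraries in the fit, and leaving out each library. Chosen after seeing the data were halved counts, shCtrl replicate 2 as the only knockdown control, thinning of all libraries to the smallest total, fits of only the 6 libraries of a hairpin comparison, leaving out each shCtrl library for the difference between the hairpins, and a covariate. The covariate was each library's score on the first principal component of the within-group residuals, called the axis score below, in a fit of all 15 libraries. With shCtrl replicate 2 alone, the lone control was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.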

Results

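Gene expression was measured in GH3 cells, a rat pituitary tumour line that secretes growth hormone and prolactin, after knockdown or overexpression of FTO, an enzyme that removes the m6A mark (a methyl group on adenosine) from RNA. The design asked how the level of FTO bears on gene expression. Total counts per library were 28856492 to 29015601 in shCtrl, 24016407 to 29614013 with shFTO-2, 22826691 to 23923323 with shFTO-3, 28794712 to 29827305 in OENC and 27218841 to 28280304 in FTOOE. Each group held 3 libraries.

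The libraries were first compared with one another. The first principal component held 63.1% of the variance and did not follow the groups alone. All 3 FTOOE libraries lay at one end (scores of -69.3, -84.5 and -108), and shCtrl replicates 1 and 3 lay with them (-89.7 and -71.0). shCtrl replicate 2 lay at 10.7, beside the OENC libraries (22.7 to 39.0) and nearer to the knockdown libraries (41.6 to 68.6). On the second component, with 10.3% of the variance, the 3 shCtrl libraries lay together (-35.9, -37.2 and -36.6). Between shCtrl replicates 1 and 2, 22.3% of the 14277 genes differed by more than 2-fold, and between replicates 2 and 3, 16.9%. The share was 6.32% between shCtrl replicates 1 and 3 and ranged from 4.01% to 10.7% within the other groups. The 500 most abundant genes took 39.9% ± 2.01 of the counts in shCtrl, 34.6% ± 0.866 with shFTO-2, 35.5% ± 0.458 with shFTO-3, 36.5% ± 0.556 in OENC and 42.7% ± 1.11 in FTOOE (mean ± SD, n = 3 each).

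**Figure D1:**
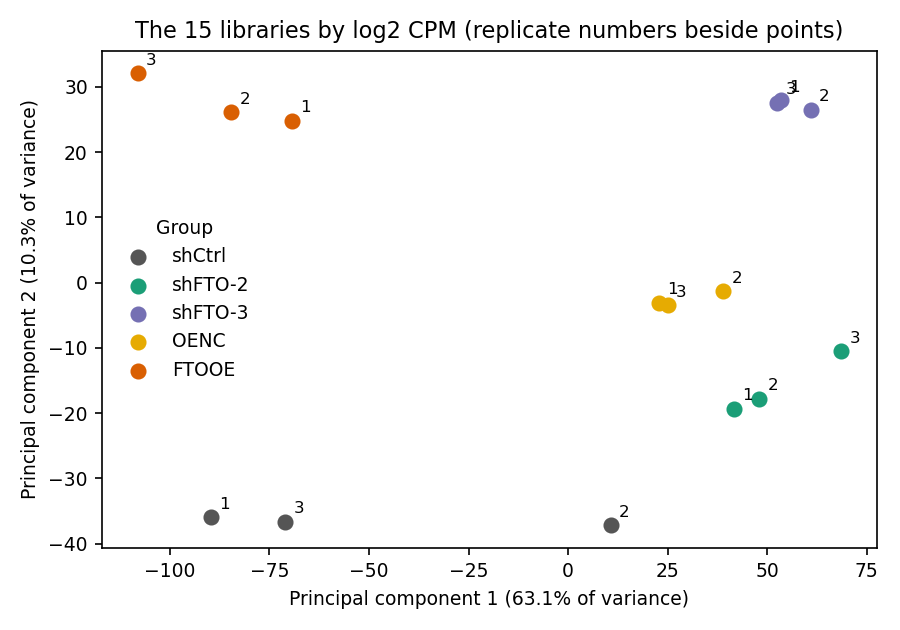
Each point is one of the 15 libraries, placed by its scores on the first (horizontal) and second (vertical) principal components of log2 CPM, coloured by group and numbered by replicate. shCtrl replicates 1 and 3 (-89.7 and -71.0) sit with the FTOOE libraries on the horizontal axis, and shCtrl replicate 2 sits at 10.7.

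The first comparison asked which genes changed with each hairpin against FTO. With shFTO-2, 3746 genes rose and 4066 fell against shCtrl among 13918 tested, and 1695 of the rises and 957 of the falls were at least 2-fold. With shFTO-3, 3983 rose and 4319 fell, 1973 and 1336 of them by at least 2-fold. With both hairpins 2770 genes were higher than in shCtrl and 3007 lower, while 183 moved in opposite directions. Of the 4205 rises and 4665 falls for the mean of both hairpins, 2821 and 3252 were also called in that direction in OENC against shCtrl. The balance of rises and falls differed with abundance. For the mean of both hairpins, 505 rose and 421 fell among 2497 genes of up to 2.38 CPM (median log2 change 0.11), and 1152 rose and 625 fell among 2855 genes with a mean of 2.39 to 13.9 CPM (median 0.28). Among 2856 genes above 82.8 CPM, 732 rose and 1401 fell (median -0.16). With library totals only the latter median was 0.00, but it still lay below that of all genes, by -0.14 with either scaling. Against shCtrl replicate 2 alone, the medians were 0.17, 0.19 and -0.12 in these groups of genes. The log ratio of shCtrl replicate 1 over 2, which differ in no treatment, had medians of -0.02, -0.19 and 0.07 in them.

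ENSRNOG00000059113 rose with both hairpins, from 0.876 ± 1.01 CPM in shCtrl to 9.77 ± 2.87 with shFTO-2 (log2 fold change 3.44, SE 0.64, adjusted p = 0.00445, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and 10.9 ± 2.18 with shFTO-3 (3.60, SE 0.65, adjusted p = 0.00223; mean ± SD, n = 3). Its shCtrl values were 0.227, 2.03 and 0.367 CPM in replicates 1, 2 and 3. In OENC, whose name holds no change of FTO, it had 5.31 ± 2.31 CPM, so much of its rise over shCtrl was also seen there. ENSRNOG00000037231 fell with both hairpins, from 13.8 ± 3.21 CPM to 2.10 ± 0.720 with shFTO-2 (log2 fold change -2.72, SE 0.36, edgeR adjusted p = 0.00158) and 1.73 ± 0.707 with shFTO-3 (7.99-fold lower, SE 0.37 on the log2 scale, edgeR adjusted p = 0.00048). All 6 knockdown libraries lay above all 3 shCtrl libraries for the former and below them for the latter, as the rule for printing them required. Such a lack of overlap held for 4850 of 5211 genes (93.1%) of that abundance called with both hairpins in one direction. The fold change of ENSRNOG00000059113 rested on the shCtrl libraries used. Without shCtrl replicate 2, its log2 fold changes were 4.996 with shFTO-2 and 5.16 with shFTO-3; with shCtrl replicate 2 alone they were 2.25 and 2.41, and with the axis score as a covariate 1.63 and 1.74. It stayed past the threshold in each (edgeR adjusted p at most 0.0204 and 0.0106 over all alternatives).

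The fold changes of the hairpins correlated across genes at r = 0.811 (Spearman's rho 0.828). Because both used the same controls, unchanged groups simulated against those controls gave r = 0.499 (highest of 20 draws 0.528), a covariance of 0.0492 against the observed 0.796, and 0 genes called in one direction with edgeR. The actual spread among the shCtrl libraries, which is wider than the simulated one, gave a covariance of 0.0984. The simulation held no shift shared by many genes, so its 0 calls do not exclude one from the controls. Independent lists of these sizes would share 1072 rises and 1262 falls. The 3 controls could not be split into parts of at least 2, so part of the excess may come from the shared controls.

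The counts depended on which shCtrl libraries served as control. With shCtrl replicate 2 alone, 4389 genes changed with shFTO-2 and 6131 with shFTO-3, and 2819 changed with both in one direction (1629 rose and 1190 fell), of which 2631 were also called with all 3 controls. With the axis score as a covariate, 3251 genes changed with shFTO-2, 5198 with shFTO-3 and 1833 with both in one direction. The fit of all 15 libraries without the covariate gave 8652, 8975 and 6569. The scores differed between shCtrl (-43.9 ± 58.9) and the knockdown groups (45.1 ± 13.4 with shFTO-2 and 47.5 ± 4.65 with shFTO-3; mean ± SD, n = 3), so this covariate also takes up part of the contrast. Without shCtrl replicate 2, the counts were 10056, 10338 and 8392. Leaving out shCtrl replicate 3 gave 4975 genes with shFTO-2 and 3445 with both hairpins, and leaving out shFTO-2 replicate 3 gave 4925 and 3806. With scaling by library totals only, 62.1% of the genes called with shFTO-2 were rises, against 48.0% with TMM factors, and for the mean of both hairpins 58.7% against 47.4%; the median of all genes then moved to 0.17 with shFTO-2, 0.13 with shFTO-3 and 0.14 for their mean. All shFTO-3 libraries and shFTO-2 replicate 3 had totals of 22826691 to 24016407 counts and all other libraries at least 27218841, so the shFTO-3 and shCtrl libraries shared no range of depth. With every library thinned to the smallest total, 8218 genes changed with shFTO-3, against 8302 unthinned.

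**Figure D2:**
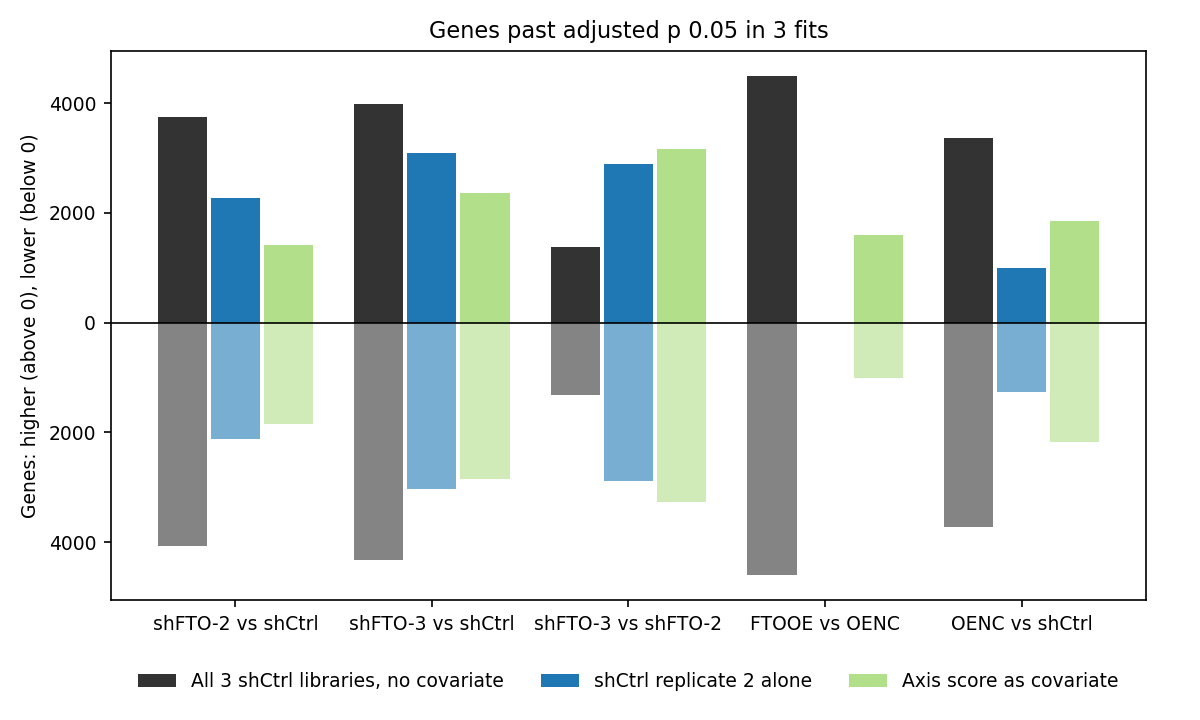
Bars give the number of genes higher (above 0) or lower (below 0) in the first-named group at an adjusted p under 0.05 in edgeR, for 5 comparisons in 3 fits. For shFTO-2 against shCtrl the rises numbered 3746 with all shCtrl libraries, 2267 with shCtrl replicate 2 alone and 1411 with the axis score as a covariate; FTOOE against OENC uses no shCtrl library, so it has no bar for the fit with replicate 2 alone.

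The hairpins were also compared directly. Between shFTO-3 and shFTO-2, 1379 genes were higher and 1320 lower with shFTO-3 among 13918 tested, 295 and 196 of them by at least 2-fold. The shCtrl libraries enter this fit through the shared estimate of the spread. In fits of only the 6 libraries compared, 5786 genes differed between the hairpins, 5351 changed with shFTO-2 and 6918 with shFTO-3. With all 15 libraries in one fit and no covariate, 3616 genes differed between the hairpins. Without shCtrl replicate 2, 5601 genes differed between the hairpins, with shCtrl replicate 2 as the only control in the fit 5776, and with the axis score as a covariate 6433. Leaving out 1 of the 6 hairpin libraries gave 1545 to 1846 genes, and 5 of these 6 values were more than 1.5 times below 2699: 1599 without shFTO-2 replicate 1, 1678 without shFTO-2 replicate 2, 1545 without shFTO-3 replicate 1, 1561 without shFTO-3 replicate 2 and 1608 without shFTO-3 replicate 3.

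The next comparison asked which genes changed in FTOOE against OENC. Of 13605 genes tested, 4501 rose and 4608 fell, and rises of at least 2-fold (1235) were fewer than such falls (2196). Among 2184 genes of up to 2.38 CPM, 331 rose and 526 fell (median log2 change -0.10). Among 2855 genes of 2.39 to 13.9 CPM, 661 rose and 1136 fell (median -0.21), and among 2856 genes above 82.8 CPM, 1300 rose and 944 fell (median 0.08). The medians of the last 2 groups lay close to those between shCtrl replicates 1 and 2 (-0.19 and 0.07). With library totals only the direction for abundant genes flipped, to 906 rises and 1393 falls (median -0.15); relative to the median of all genes they stayed higher, by 0.09 with either scaling.

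ENSRNOG00000053044 rose from 0.629 ± 0.289 CPM in OENC to 13.9 ± 7.61 in FTOOE (log2 fold change 4.43, SE 0.46, edgeR adjusted p = 2.22e-05; mean ± SD, n = 3). ENSRNOG00000045728 fell from 12.4 ± 4.64 to 0.440 ± 0.144 CPM (-4.83, SE 0.37, edgeR adjusted p = 5.86e-06). Both genes also differed among the shCtrl libraries, at 8.67, 0.610 and 5.61 CPM for ENSRNOG00000053044 and 0.189, 6.21 and 0.807 CPM for ENSRNOG00000045728 in replicates 1, 2 and 3. With the axis score as a covariate, neither passed the edgeR test: the log2 fold change was 0.84 (adjusted p = 0.357) for ENSRNOG00000053044 and -1.07 (adjusted p = 0.182) for ENSRNOG00000045728. Over all alternatives the adjusted p ranged from 1.28e-25 to 0.357 for ENSRNOG00000053044 and from 5.69e-34 to 0.182 for ENSRNOG00000045728. ENSRNOG00000037231, lowered by both hairpins, also fell in FTOOE, from 14.9 ± 3.47 to 2.27 ± 0.388 CPM (log2 fold change -2.73, SE 0.23, edgeR adjusted p = 7.41e-06). The other printed identifiers moved oppositely in the other experiment, past the threshold. ENSRNOG00000059113 fell in FTOOE (log2 fold change -3.52). ENSRNOG00000053044 fell with shFTO-2 (-3.31, SE 0.93, edgeR adjusted p = 0.017) and shFTO-3 (-3.46, SE 0.96, edgeR adjusted p = 0.0137). That fall rested on shCtrl replicates 1 and 3, as shCtrl replicate 2 (0.610 CPM) lay within the range of the knockdown libraries (0.164 to 0.915 CPM). ENSRNOG00000045728 rose with shFTO-2 (2.95, SE 0.88) and shFTO-3 (2.99, SE 0.88). Fold changes of printed identifiers in the other experiment were not rerun under the alternatives.

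The axis scores separated FTOOE (-76.6 ± 24.1) from OENC (27.8 ± 8.49; mean ± SD, n = 3 each), so a covariate of these scores removes part of the contrast by construction. With this covariate, 1590 genes rose and 1014 fell in FTOOE, and 2215 of these 2604 were also called in one direction without it. The share of rises was then 61.1%, against 49.4% without the covariate. With library totals only, 3076 rose and 6036 fell (33.8% rises), and the median of all genes moved to -0.24.

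**Figure D3:**
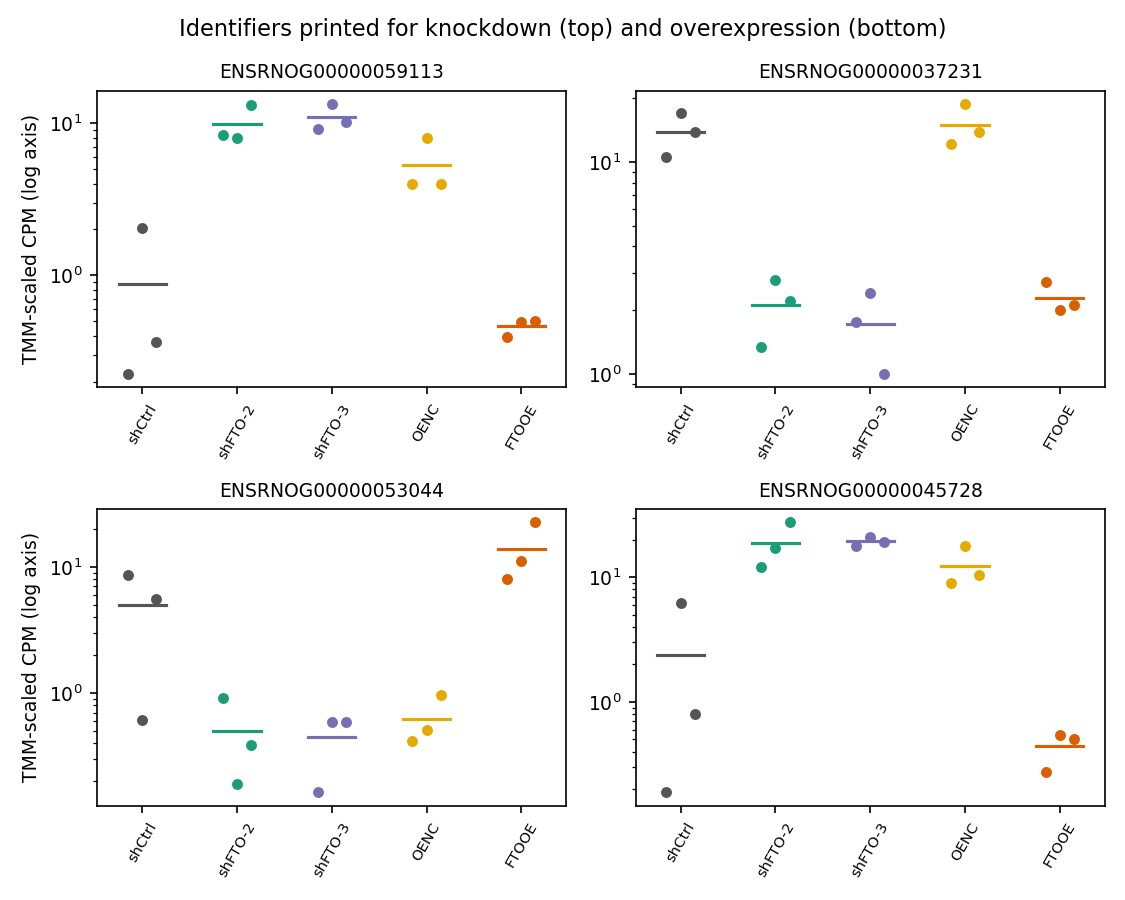
Points give TMM-scaled CPM on a log axis for each library of the 5 groups, and lines give the mean of 3 libraries. ENSRNOG00000037231 was lower in all knockdown libraries than in shCtrl and lower in FTOOE (2.27 ± 0.388) than in OENC (14.9 ± 3.47), while the other genes also differ among the shCtrl libraries.

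The control groups were compared as a background. Between OENC and shCtrl, which both lack a change of FTO in their names, 3363 genes were higher and 3725 lower in OENC among 14277 tested, 1245 and 637 of them by at least 2-fold. These fold changes correlated across genes with those of the mean knockdown at r = 0.871, with the shCtrl libraries shared. Unchanged groups simulated against those controls gave r = 0.587 (highest of 20 draws 0.624), a covariance of 0.0478 against the observed 0.641, and 0 genes called in both in one direction with edgeR. The actual spread among the shCtrl libraries gave a covariance of 0.104. Here too the simulation held no shift shared by many genes, so its 0 calls do not exclude one from the controls. In both comparisons 2821 genes rose and 3252 fell, of 4205 rises and 4665 falls for the mean knockdown. Independent lists would share 1012 and 1244, which leaves out the shared controls, so part of the excess may come from them. Against shCtrl replicate 2 alone, 1000 genes were higher and 1269 lower in OENC. With the axis score as a covariate 4024 genes differed, and in a fit of only these groups 2957. With library totals only, 59.8% of calls were higher in OENC, against 47.4% with TMM factors.

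The last comparison asked whether knockdown and overexpression moved genes in opposite directions. Of 6433 genes called in both, 5756 (89.5%) moved oppositely: 2815 rose in knockdown and fell in FTOOE, and 2941 fell in knockdown and rose in FTOOE, where independent lists would share 1408 and 1526. Another 297 rose in both and 380 fell in both. The odds ratio for moving in one direction was 0.0137 in Fisher's exact test, whose p-value was too small for the software to represent; genes are not independent, so it overstates the evidence. Across 13472 genes the fold changes correlated at r = -0.712 (Spearman's rho -0.692), and the comparisons share no library. Without a filter on low counts r was -0.367, and without shCtrl replicate 2 it was -0.786. A direct test of the difference between overexpression and knockdown called 10551 of 14277 genes (5404 higher and 5147 lower in overexpression relative to knockdown).

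The opposition was weaker with shCtrl replicate 2 as the only knockdown control: r was -0.340 (rho -0.385), and 3070 of 3914 genes called in both (78.4%) moved oppositely. The axis score as a covariate acts on all 15 libraries, FTOOE and OENC included, so a weaker opposition is partly built into it. With the covariate, r was -0.301, and 126 and 325 genes moved oppositely (40.4% of those called in both), while 318 rose in both and 347 fell in both. The fit of all 15 libraries without the covariate gave r = -0.649 and 6014 opposite genes. The direct test then called 1396 genes, of which 65.5% were higher in overexpression relative to knockdown, against 51.2% without the covariate and 36.5% with library totals only. Log ratios between shCtrl libraries, which differ in no treatment, correlated with the FTOOE fold changes at r = 0.824 for replicate 1 over 2, -0.801 for replicate 2 over 3 and 0.312 for replicate 1 over 3.

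**Figure D4:**
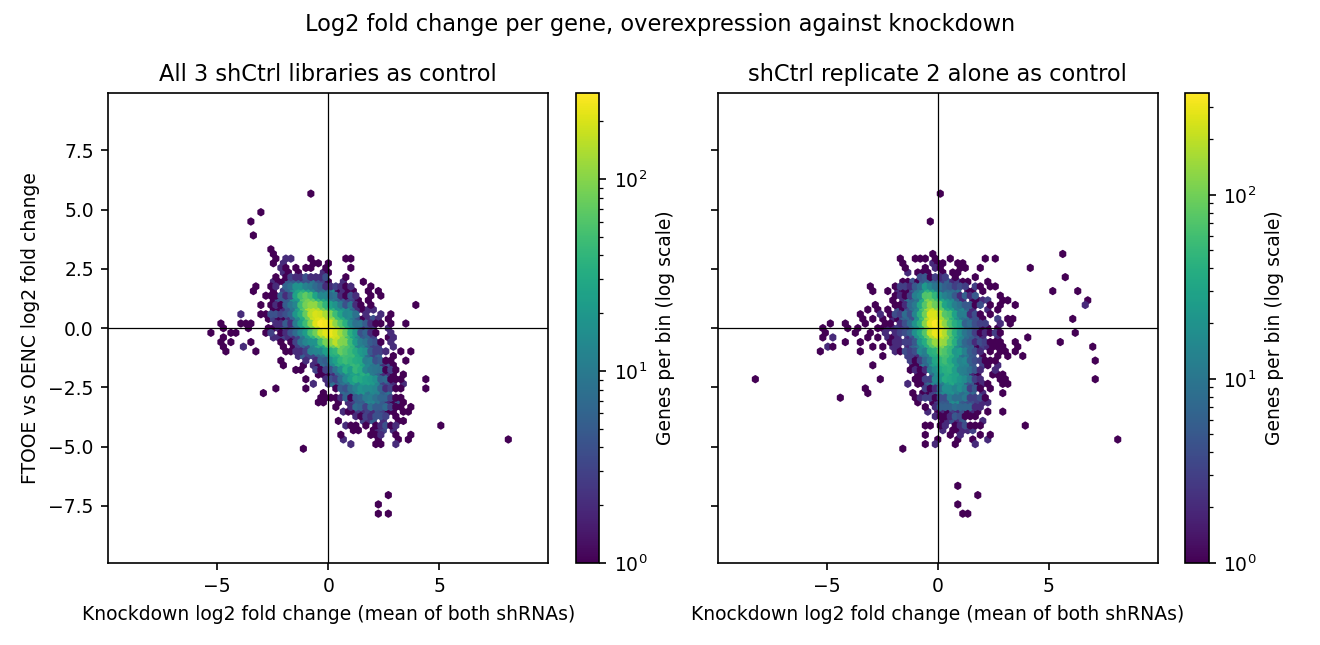
Hexagons give the number of genes (log colour scale) by log2 fold change in knockdown, as the mean of both hairpins (horizontal), and in FTOOE against OENC (vertical). The left panel uses all shCtrl libraries (r = -0.712) and the right panel shCtrl replicate 2 alone (r = -0.340).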

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

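Thinning to one depth and the fit of only the 6 hairpin libraries were tests chosen after the data were seen. The difference between the hairpins was picked out because groups under the same contrast differed in a direct test: edgeR called 2699 of 13918 genes between shFTO-3 and shFTO-2. The shFTO-3 libraries were shallower (22826691 to 23923323 counts) than shFTO-2 replicates 1 and 2 (28285671 and 29614013). After thinning every library to the smallest total, 2661 genes were called, which argues against depth as the source. With only the 6 hairpin libraries 5786 genes were called. Hairpin sequence, the degree of knockdown and the cultures used stay open as untested explanations, since Fto was not analysed here. The 6 libraries allow 10 splits, too few for a share under 0.05; the real split called 2699 genes and the highest other called 0 in edgeR (156 at an unadjusted p under 0.05).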

How the results depend on the processing

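Of 247 alternative values of counts and correlations, 193 stayed close to the reported value (within 1.5 times for counts, within the leave-one-out SD for correlations) and 54 moved further. Of the correlations, 0 changed sign. Counts have no sign, and this rule does not cover their balance of rises and falls. FTOOE against OENC with library totals only was thus scored as close, with 3076 rises and 6036 falls against 4501 and 4608. The printed identifiers had 120 alternative fold changes, each in the experiment the identifier was printed for. Of these, 118 stayed past the threshold in the same direction, and 2, given in the report, lost their call with the axis score as a covariate. Counts are listed for shFTO-2, shFTO-3 and their mean against shCtrl, shFTO-3 against shFTO-2, FTOOE against OENC, OENC against shCtrl, overexpression minus knockdown, both hairpins in one direction, and opposite in knockdown and overexpression. With a minimum absolute log2 fold change of 1 they were 2652, 3309, 2963, 491, 3431, 1882, 6634, 1925 and 1785, because fewer genes can pass. With the axis score as a covariate they were 3251, 5198, 4129, 6433, 2604, 4024, 1396, 1833 and 451. With shCtrl replicate 2 alone, the values that moved were 4389, 5290 (mean of both hairpins), 5776 (between hairpins), 2269 (OENC), 2819 (both hairpins) and 3070 (opposite). Fits of only the groups compared gave 2957 genes for OENC against shCtrl and 5786 between the hairpins. The correlations of the hairpins, and of knockdown with overexpression, were 0.647 and -0.367 without a filter, 0.851 and -0.754 with a stricter filter, 0.863 and -0.771 for genes of mean log2 CPM of at least 5, 0.724 and -0.340 with shCtrl replicate 2 alone, and 0.663 and -0.301 with the axis score as a covariate. The latter correlation was -0.649 with all 15 libraries in one fit and -0.746 with halved counts. Apart from the fold minimum and the smaller sets of libraries, the cause was not tested.

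Leaving out each library of the groups compared, and for the difference between the hairpins also each shCtrl library (added after seeing the data), gave 4925 to 10056 genes for shFTO-2, 6336 to 10338 for shFTO-3, 6592 to 10522 for their mean, 1545 to 5601 between the hairpins, 8174 to 9140 for FTOOE, 4833 to 9294 for OENC against shCtrl, 10040 to 11123 for overexpression minus knockdown, 3445 to 8392 for both hairpins and 4245 to 6999 for opposite moves. The correlations ranged from 0.759 to 0.886 and from -0.786 to -0.631. The replicate block gave 7446, 8017, 8576, 2111, 8559, 7138, 10419, 5542 and 5514 genes, none over 1.5 times from the reported counts. Replicate numbers did not pair libraries: 2 of 12 same-numbered pairs within each experiment correlated above 0.1 (range -0.215 to 0.218), as did 5 of all 30 pairs (-0.363 to 0.272), and 6 of 15 libraries correlated best with their own number. Alternatives for Fto and for the gene lists were not run because no identifier matched a symbol. With 3 libraries per group, 1.5-fold changes in the hairpin comparisons were mostly missed on simulated counts (13.4% and 10.2% recovered). Few genes were changed there (97 and 98 by 1.5-fold), so the adjustment was stricter than with the 7812 and 8302 genes called here. These rates do not carry over to the reported comparisons, but a gene not called may still have changed.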

Other observations

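The fits with shCtrl replicate 2 alone and with the axis score as a covariate, thinning to one depth, and the tests of a wrong label, of the shCtrl totals and of the FTO level were chosen after the data or the value concerned were seen. In each of 3 fits (all shCtrl libraries, shCtrl replicate 2 alone, and the covariate, which acts on all 15 libraries), edgeR called 744 genes up and 749 down with both hairpins. The median log2 changes were 1.06 with shFTO-2 and 1.27 with shFTO-3 for the former, and -0.76 and -0.85 for the latter. Of the 741 raised genes tested in FTOOE against OENC, 461 fell and 92 rose there; of the 747 lowered genes, 443 rose and 104 fell. With the covariate, 71 of the raised genes fell and 108 rose in FTOOE, and 142 of the lowered genes rose and 104 fell. Of all genes called in FTOOE in that fit 61.1% rose, so these counts show no opposition beyond that share. ENSRNOG00000059113 and ENSRNOG00000037231 belong to these sets.

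On the second principal component the FTOOE libraries (24.8, 26.1 and 32.1) lay beside the shFTO-3 libraries (28.0, 26.5 and 27.6), although their labels name opposite changes of FTO. With the first component removed, the library nearest to FTOOE replicate 1 was FTOOE replicate 2, that nearest to FTOOE replicate 2 was shFTO-3 replicate 3, and that nearest to FTOOE replicate 3 was shFTO-3 replicate 2 (r = 0.286). Log ratios within other groups also correlated with fold changes of the other experiment, at up to 0.397 (shFTO-2 replicate 1 over 3) and -0.304 (OENC replicate 1 over 2), and at 0.372 for FTOOE replicate 1 over 3. For shFTO-3 they ranged from -0.181 to 0.156.

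The opposite course of knockdown and overexpression fold changes (r = -0.712) was weighed first. After thinning to one depth r was -0.722, which argues against a difference in depth. With shCtrl replicate 2 as the only knockdown control r was -0.340, and without that library it was -0.786. Replicate 2 is the shCtrl library nearest to the knockdown libraries on the first component, which also separates FTOOE from OENC. A weaker r may thus be partly built into its choice. The spread among the shCtrl libraries may account for part of the opposition. It cannot be told apart from an effect of FTO for the rest, because 1 control library cannot show how controls vary. An effect of the FTO level itself stays open, since 0 identifiers could be matched to a symbol and Fto was not analysed here. Only the real one of 40 drawn splits gave as many opposite genes (1 of 40, real 5756, highest other 0 in edgeR). A gene counts only if called in both experiments, and every other split of FTOOE and OENC called 0 genes. Some draws kept FTOOE and OENC as whole groups, with labels kept or exchanged. In these the knockdown libraries were shuffled, and they also gave 0 opposite genes. The draws therefore say nothing on direction and exclude none of these explanations.

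The distance of shCtrl replicate 2 from shCtrl replicates 1 and 3 was weighed next; over all components its nearest library was OENC replicate 1 (r = 0.980), not a shCtrl library (0.950 and 0.962). With the first component removed, its lowest correlation with the other shCtrl libraries (0.405) exceeded its highest with any other group (0.0783) by 0.327, which argues against a library of another group in this series under a wrong label; a mixed sample stays open. The shCtrl totals differed by a factor of 1.01, which argues against depth. Without the 100 most abundant genes, 22.4% of genes still differed by more than 2-fold between replicates 1 and 2, against 6.36% between replicates 1 and 3. The difference was thus not confined to those genes. TMM factors already trim genes with extreme ratios, so leaving out 100 genes could hardly move this share. The test therefore does not decide on a few dominant genes. A difference between cultures or preparations stays open, as the labels give neither, and no biological explanation was tested.

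Other splits of the libraries were counted for the remaining results. For shFTO-2 against shCtrl, shFTO-3 against shCtrl, FTOOE against OENC and OENC against shCtrl, 10 splits are too few for a share under 0.05. The real splits called 7812, 8302, 9109 and 7088 genes and the highest others called 0 in edgeR (3231, 1759, 63 and 5075 at an unadjusted p under 0.05). For the mean of both hairpins, 1 of 84 splits was as large (real 8870, highest other 5528, with the shFTO-3 libraries in place of the controls). The same held for both hairpins in one direction (1 of 100 drawn, real 5777, highest other 1726). It also held for overexpression minus knockdown (1 of 40 drawn, real 10551, highest other 5552). That highest other draw exchanged the labels of FTOOE and OENC as whole groups, so it kept their difference. In each result the split by label called the most genes, but the shCtrl libraries did not group by label alone. The 3231, 1759 and 5075 genes came from splits with a library of the other group in place of shCtrl replicate 2. For the mean of both hairpins, shFTO-2 replicates 1 and 2 in that place gave 2753 and 847 genes. There shFTO-2 replicate 3 and each shFTO-3 library gave 0. The splits cannot exclude chance differences between cultures or preparations, as the libraries of a group may be technical replicates.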
